A study of Mus musculus with 2 samples.

How the data were processed

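Small RNA was sequenced from gastrocnemius, the large calf muscle, of male mice of the B6CASTF1/J cross at 14 days of age. The B6CASTF1/J mouse is the first-generation offspring of a C57BL/6 and a CAST/EiJ parent. The labels give 1 group of 2 biological replicates, each with 1 library, and a size range under 30 nt. Both labels carry the same donor identifier and a description that mentions several males, and they do not say whether a replicate is 1 animal or a pool of animals, or whether the replicates share animals. Every spread given here, the biological coefficient of variation included, is therefore the spread between these 2 samples, which may be partly technical and, if they are pools, would be expected to be smaller than that between animals. There was no second tissue, age, sex or treatment, so no condition was compared with another.

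The values deposited for each library were whole-number read counts per microRNA gene, not normalized and with 1 library per table, in 3 columns for reads on either strand, on the gene's own strand and on the opposite strand. Per the labels and the notes deposited with the tables, the counts were made on genome build mm10 with the M21 gene annotation. The aligner, the counter, their versions and the adapter trimming were not given in the sources used here. Each deposited table listed 2202 microRNA genes, and 4 further lines of counts that named no gene and stayed out of library sizes and tests. Those lines held the unmapped reads, the reads that mapped to several loci, the reads that mapped once outside the annotated genes and the reads under more than 1 gene. A read that mapped to several loci was in no gene's count, so a microRNA encoded by identical copies at different loci is under-represented by an amount that these tables do not give. The counts are per hairpin gene and do not separate the 5′ from the 3′ mature arm. All 2202 identifiers were found in the GENCODE vM21 annotation of the same build, which gave symbols, coordinates, strands and host genes, and 1 symbol was shared by a pair of identifiers.

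The column of counts on the gene's own strand was used throughout. With either strand counted, a read under a pair of microRNA genes annotated on opposite strands is ambiguous and is left out, and 64 genes had such a partner. Replicate 1 held 10056843 reads, of which 2599794 (25.9%) were unmapped, 4421485 (44.0%) mapped to several loci, 291907 (2.90%) mapped once outside the genes and 2743657 (27.3%) were assigned to a gene. Replicate 2 held 8189059 reads, with 1492144 (18.2%), 4266018 (52.1%), 219643 (2.68%) and 2211254 (27.0%) in the same classes. CPM (counts-per-million), the count scaled by all counts assigned to a microRNA gene, was computed here from the deposited counts. A gene with no count could hold up to 3 counts at this depth, which is 1.09 CPM in replicate 1 and 1.36 CPM in replicate 2. Intervals for shares are 95% Wilson intervals. Reads made by PCR are not independent molecules, so intervals and these limits cover counting error only.

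Gene lists were fixed before the data were examined. They were the myomiR list of muscle-enriched microRNAs and a list for muscle growth and satellite cells, lists of microRNAs known from other cells or tissues (erythroid, leukocyte, endothelial, smooth muscle, fibroblast and connective tissue, neuron, glia, liver and gut, epithelial), and lists for the pancreas and for the X-linked cluster of the testis. The others were the imprinted Dlk1-Dio3 cluster, let-7, miR-17-92 with its paralogs, miR-30, the microRNAs within Hox clusters, miR-99/100 with miR-125, the repeated miR-297, miR-466, miR-467 and miR-669 name families, and the loci whose mature sequence is identical at another locus. The genes named were also fixed by rule. The rule took the 15 genes with the highest mean CPM, every myomiR in the table, up to 4 members of each other list at 10 CPM or more in both libraries, and the 5 largest log2 ratios in each direction between the libraries among genes past the test. Where a list had no gene at 10 CPM, its most abundant member was named. Genes named outside the rule were chosen after their values were seen.

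The libraries were compared over genes at 10 CPM or more in both. Library sizes were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, and the common biological coefficient of variation came from edgeR's estimateDisp with an intercept only, with a 95% interval from 100 bootstrap resamples of the genes. Each gene's counts were compared by a two-sided exact binomial test given the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 and a difference of at least 2-fold. That test compares these 2 libraries and covers counting error only. A log2 ratio is replicate 2 minus replicate 1 on log2(CPM + 1) with TMM sizes. The median log2 ratio of a list with 3 or more members was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description with no p-value. The random lists take no account of members that encode the same mature microRNA or lie in 1 cluster. On counts simulated with counting error alone, the adjusted binomial test with no fold threshold called 3.61% of 166 unchanged genes. It called 100% of 40 genes changed 2-fold and 100% of 41 genes changed 4-fold. These rates do not apply to libraries that vary beyond counting error, as these did. Simulated coefficients of variation of 0, 0.1 and 0.2 were recovered as 0.00988, 0.0955 and 0.187 over 247 genes.

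Alternatives were counts on either strand, library sizes from total counts or from the median of ratios of DESeq2 1.42.0, other expression thresholds, totals without the most abundant gene or without repeated loci, each replicate left out, no fold threshold, and edgeR's exact test with the common dispersion. Shares of all mapped reads, and shares without loci that have an exact stretch of 20 bases in common with another microRNA locus, were added after seeing the data. Genes within 10 kb of each other on 1 strand were taken as a cluster. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No read sequences, isoforms of mature microRNAs or alleles of the parental strains were analysed here.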

Results

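MicroRNAs were counted in gastrocnemius of 14-day-old male B6CASTF1/J mice, in 1 group of 2 biological replicates. The question this design addresses is which microRNA genes make up the small RNA of the growing calf muscle and how far the replicates differ. Of 10056843 reads in replicate 1 and 8189059 in replicate 2, 2743657 and 2211254 were assigned to a microRNA gene on its own strand. Values are means ± SD over the 2 libraries (n = 2) unless a replicate is named. Of the 2202 genes in the table, 258 reached 10 CPM in both libraries, 367 reached 1 CPM and 178 reached 100 CPM. A count in at least 1 library was found for 629 genes, and the other 1573 had none. Coordinates are on mm10.

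**Figure D1:**
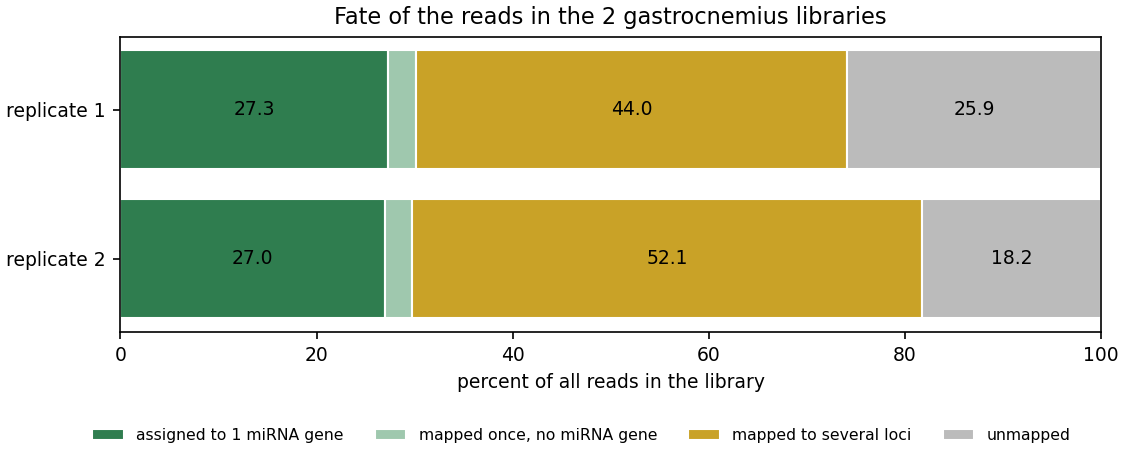
Share of all reads in each library, in percent, by where the reads mapped; each bar is 1 replicate. Reads mapped to several loci were 44.0% in replicate 1 and 52.1% in replicate 2, and reads assigned to 1 microRNA gene were 27.3% and 27.0%.

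The order of abundance below covers counts assigned to a gene. It leaves out reads that mapped to several loci, 44.0% of all reads in replicate 1 and 52.1% in replicate 2. Within it, Mir378a was the most abundant microRNA gene, at 117291 CPM ± 8973 (SD, n = 2). It lies in an intron of Ppargc1b, which encodes a transcriptional coactivator of mitochondrial and oxidative metabolism (ENSMUSG00000105200.1, chromosome 18, 61397835 to 61397900). Mir126a followed at 89259 CPM ± 12484, and it lies in an exon of a transcript of Egfl7, whose product is secreted by endothelial cells (ENSMUSG00000065540.1, chromosome 2, 26591357 to 26591429). Mir127 of the imprinted Dlk1-Dio3 cluster was at 75510 CPM ± 2663 (ENSMUSG00000070076.2, chromosome 12, 109592846 to 109592915). The skeletal muscle microRNA Mir206 was at 68099 CPM ± 267 (ENSMUSG00000065559.1, chromosome 1, 20679010 to 20679082), so Mir378a stood at 1.72 ± 0.139 times Mir206.

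The next genes were Mir411 at 55294 CPM ± 6202, Mirlet7i at 50055 CPM ± 4426, and Mirlet7g, in an intron of Wdr82, at 46287 CPM ± 5137. Mir143, known from smooth muscle, was at 34797 CPM ± 1266. Mir23b was at 27505 CPM ± 2120 and its paralog Mir23a at 21316 CPM ± 1742, with Mir379 between them at 21851 CPM ± 1002. Mirlet7d (19583 CPM ± 1176), Mir99a (18449 CPM ± 2927), Mir26b in an intron of Ctdsp1 (18297 CPM ± 1423) and Mir335 in an intron of the imprinted gene Mest (17671 CPM ± 1724) completed the 15 highest. The 10 most abundant genes held 58.6% ± 0.210 of all assigned counts, and with either strand counted that share was 49.5%, because Mir378a and Mir126a each had a microRNA gene annotated on the opposite strand and kept 0 and 1 counts per library.

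**Figure D2:**
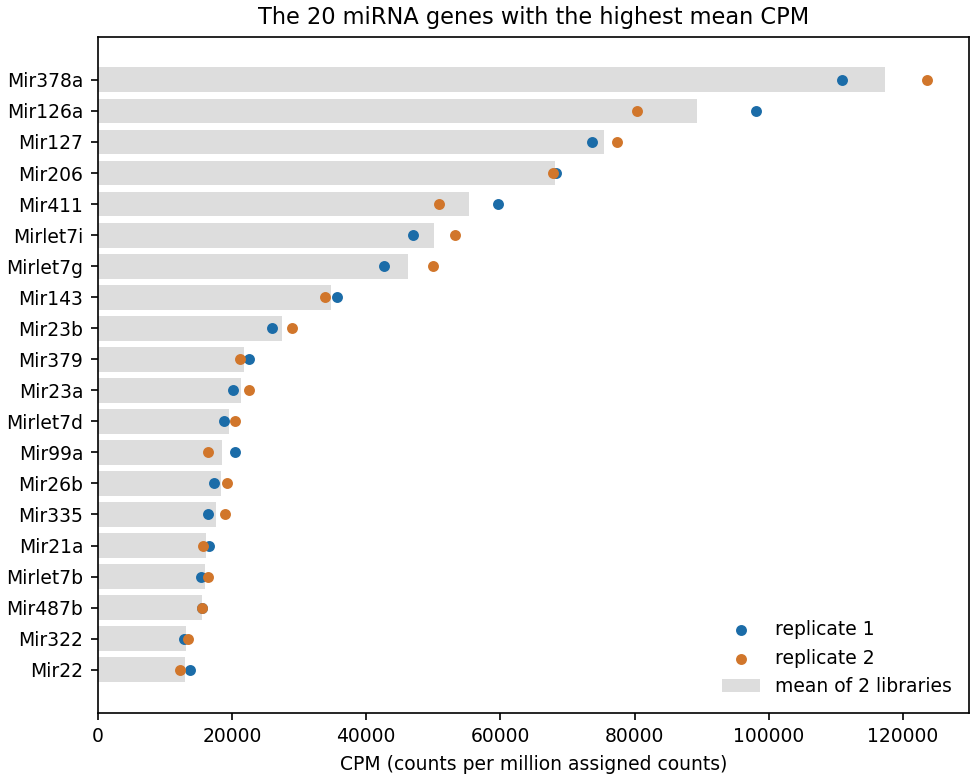
CPM of the 20 microRNA genes with the highest mean; bars start at 0 and give the mean of the 2 libraries, and points give each replicate. Mir378a is at the top with a mean of 117291 CPM, and the points of Mir206 nearly coincide at 68288 and 67909 CPM.

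The myomiRs, microRNAs enriched in striated muscle, held 6.94% ± 0.0228 of counts. By assigned counts, nearly all of that was Mir206, which is characteristic of skeletal muscle and regenerating fibres. Mir486, in an intron of Ank1, was at 611 CPM ± 55.7. Mir499, in an intron of the myosin heavy chain gene Myh7b, was at 277 CPM ± 85.7, and Mir208b, in an intron of the slow fibre myosin gene Myh7, was at 84.3 CPM ± 0.314. Mir1a-2 was counted at 246 CPM ± 68.2, Mir133b at 26.2 CPM ± 7.69, Mir133a-1 at 17.0 CPM ± 1.69, Mir3107 at 12.6 CPM ± 1.35, Mir1a-1 at 12.2 CPM ± 3.85 and Mir133a-2 at 1.82 CPM ± 0.00952. Mir206 was thus 2716 ± 807 times Mir133b, its neighbour in the same host transcript.

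The Mir1a, Mir133, Mir486 and Mir3107 values stand beside a limit whose size was not measured. Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir133b each have a 20-base stretch in common with another microRNA locus, and reads that mapped to several loci are in no gene's count. Such a stretch does not give the size of the loss, since the most abundant gene, Mir378a, has one too. Mir486 and Mir3107 overlap on opposite strands, and the search for such stretches left out overlapping genes. Both are on the list of loci whose mature sequence is identical at another locus, so the limit holds for them too. Mir208a, in an intron of the cardiac myosin gene Myh6, had 7 counts in replicate 1 and 0 in replicate 2. Mir1b had 3 and 1, and Mir133c had no count in either library, which allows up to 1.09 CPM in replicate 1 and 1.36 CPM in replicate 2. Of the 13 myomiR genes in the table, 12 had a count and 8 reached 10 CPM in both libraries.

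The list for muscle growth and satellite cells held 15.3% ± 0.740 of counts, most of it Mir378a. With either strand counted, which drops Mir378a, the list held 4.63%. Mir322, an X-linked microRNA known to promote cell cycle exit of myoblasts, was at 13175 CPM ± 388. Mir22 was at 12977 CPM ± 980, and Mir27b, which targets the muscle progenitor factor Pax3, was at 4750 CPM ± 687. All 18 genes of this list had a count, and 15 reached 10 CPM in both libraries.

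The imprinted Dlk1-Dio3 cluster, whose microRNAs are transcribed from the maternal chromosome, held 24.4% ± 0.657 of counts. Besides Mir127, Mir411 and Mir379, it was led by Mir487b at 15539 CPM ± 71.3. Of 56 genes on this list, 51 had a count and 46 reached 10 CPM in both libraries. The 55 members on chromosome 12 span 109544541 to 109747960, a stretch of 203 kb, and 14 of the 50 most abundant genes by assigned counts belonged to the list. Levels within the cluster were far apart, from Mir127 at 75510 CPM to Mir410 at 261 CPM ± 86.2 and Mir3544, annotated on the opposite strand, at 19.8 CPM ± 7.55.

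**Figure D3:**
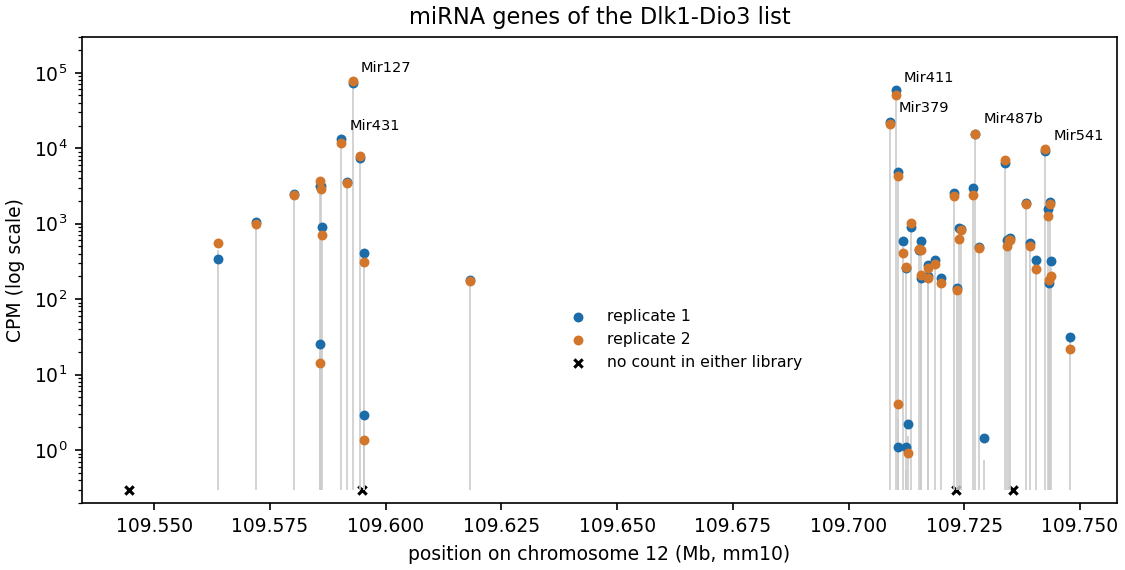
CPM on a log scale of the microRNA genes of the Dlk1-Dio3 list against position on chromosome 12 in Mb (mm10); points give each replicate, grey lines the mean, and crosses genes with no count in either library, while a library with no count for a gene has no point. Mir127 at 75510 CPM and Mir411 at 55294 CPM are the highest points of the left and right groups.

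The let-7 family, which accumulates as tissues differentiate, held 14.3% ± 1.24 of counts, with all 12 genes at 10 CPM or more in both libraries. The family was led by Mirlet7i, Mirlet7g, Mirlet7d and Mirlet7b, the last at 15931 CPM ± 770. Mirlet7f-2 was at 3635 CPM ± 408, while the loci that encode the same mature let-7a, let-7c or let-7f elsewhere were lower. Mirlet7d was 79.1 ± 1.35 times its neighbour Mirlet7a-1. The counts of Mirlet7a-1 and the other loci with an identical mature sequence elsewhere leave out reads that mapped to several loci. Their values, and this ratio, do not show how far let-7a, let-7c or let-7f is expressed.

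MicroRNAs of other cells in the muscle were present at different levels. The endothelial list held 8.93% ± 1.25 of counts, nearly all of it Mir126a, and 5.32e-05% with either strand counted, which drops Mir126a. The smooth muscle list held 3.58% ± 0.126, with Mir143 at 34.3 ± 1.41 times Mir145a, which was at 1015 CPM ± 4.69. The fibroblast and connective tissue list held 2.18% ± 0.140, led by Mir21a, a microRNA of many cell types, at 16074 CPM ± 598, with Mir214 at 4223 CPM ± 728, the cartilage microRNA Mir140 at 1442 CPM ± 67.1 and Mir199a-2 at 40.7 CPM ± 1.33. The leukocyte list held 0.155% ± 0.000151, with Mir146 at 535 CPM ± 48.3, Mir155 at 350 CPM ± 29.2, Mir150 at 322 CPM ± 14.0 and Mir142 at 203 CPM ± 6.83.

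The erythroid list held 0.0384% of counts in replicate 1 (95% Wilson interval 0.0361 to 0.0408) and 0.0571% in replicate 2 (0.0540 to 0.0603). Mir451a, abundant in red blood cells, was at 387 CPM ± 108 and its cluster partner Mir144 at 89.9 CPM ± 24.5, a ratio of 4.31 ± 0.0236; with either strand counted, which drops Mir451a, the list held 0.0117%. The neuron list held 0.104% ± 0.0118, most of it Mir128-1 at 720 CPM ± 70.6 and Mir128-2 at 208 CPM ± 18.6, and the glia list held 0.0380% ± 0.00234, most of it Mir338 at 366 CPM ± 19.4. The neuron list held 0.00424% without the loci whose mature sequence is identical elsewhere, such as Mir128-1, and the glia list 0% with either strand counted, which drops Mir338. Other lists were lower. The liver and gut list held 0.0150% ± 0.00131, with Mir122 at 120 CPM ± 16.8, Mir192 at 15.2 CPM ± 2.26 and Mir194-2 at 13.7 CPM ± 0.778. The epithelial list held 0.0158% ± 0.00142, with Mir203 at 129 CPM ± 24.6, and the pancreas list 0.00140% ± 0.0000697, led by Mir217 at 8.08 CPM ± 0.0860. The testis X-linked cluster had 1 count in replicate 1 and 2 in replicate 2 over 19 genes, with Mir743 at 1 count in each, which is under the limit that a count of 0 allows.

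The microRNAs encoded within the clusters of Hox genes, which set position along the body axes, held 2.27% ± 0.281 of counts. They were led by Mir10b (12561 CPM ± 2182), with Mir196b at 5827 CPM ± 685, Mir10a at 3095 CPM ± 44.2 and Mir196a-2 at 1013 CPM ± 46.3. The miR-99/100 and miR-125 list held 2.83% ± 0.354, with Mir100 at 5798 CPM ± 367, Mir125a at 2278 CPM ± 40.0 and Mir99b at 1377 CPM ± 185. The miR-30 family held 2.24% ± 0.0957, with Mir30d at 10068 CPM ± 50.1, Mir30a at 8632 CPM ± 485, Mir30e at 3430 CPM ± 539 and Mir30b at 139 CPM ± 6.63. The growth-associated miR-17-92 cluster with its paralogs held 0.591% ± 0.0210, led by Mir17 (2042 CPM ± 80.2) and Mir93 (1523 CPM ± 223), with Mir20a at 761 CPM ± 5.51 and Mir106b at 533 CPM ± 28.7.

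The miR-297, miR-466, miR-467 and miR-669 name families, repeated loci, held 0.0566% ± 0.000204 of counts, and 9 of their 81 genes had any count. Without loci that have 20 bases in common with another, their share was 0%. Reads that mapped to several loci are in no gene's count, so these values do not show how far the families are expressed. Their leading members, in introns of Sfmbt2, were Mir467e at 213 CPM ± 1.00, Mir467d at 169 CPM ± 1.66, Mir669o at 68.2 CPM ± 4.65 and Mir669c at 47.3 CPM ± 1.08. The 61 loci whose mature sequence is identical at another locus held 1.13% ± 0.0672 together, with 33 at 10 CPM in both libraries. The highest of them were Mirlet7f-2, Mir196a-2, Mir181b-2 at 775 CPM ± 49.5 and Mir128-1.

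The replicates were then compared with each other over the 258 genes at 10 CPM in both. At least 2-fold differences were found for 3 genes, all higher in replicate 2. Mir137, enriched in neurons, had 14.2 CPM in replicate 1 and 47.9 CPM in replicate 2, a log2 ratio of 1.64 (exact binomial test, adjusted p = 1.14e-10). Mir1249 had 13.5 and 37.5 CPM, a log2 ratio of 1.37 (exact binomial test, adjusted p = 6.67e-07), and Mir138-1, also enriched in neurons, had 23.7 and 59.2 CPM, a log2 ratio of 1.24 (exact binomial test, adjusted p = 9.90e-09). These genes rest on 37 to 131 counts per library, and at 100 CPM or more in both libraries 0 genes differed 2-fold by either the binomial test or edgeR's exact test, with 0 at an unadjusted p in edgeR. With every gene that had a count admitted, 10 genes passed the binomial test, 8 higher and 2 lower in replicate 2, and 3 passed edgeR's exact test. Among genes past the exact binomial test, the next positive log2 ratios were those of Mir7j (0.94) and Mir598 (0.85), and the largest negative ones those of Mir3544 (−0.80), Mir410 (−0.73), Mir499 (−0.69), Mir101a (−0.66) and Mir380 (−0.59), all short of 2-fold.

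With no fold threshold, 131 of the 258 genes differed by more than counting error (exact binomial test, Benjamini-Hochberg), 49 higher and 82 lower in replicate 2. With library sizes from total counts the split was 67 higher and 66 lower. The chi-square of the counts was 82.6 per degree of freedom over 257 degrees of freedom, so the counts did not agree within sampling noise and the libraries were kept as 2 samples. The common biological coefficient of variation was 12.8% (95% bootstrap interval 11.2 to 14.5), between samples that may each be 1 animal or a pool, which the labels do not say. That interval resamples genes within these 2 libraries and does not cover how the value would vary with other samples. The median absolute log2 ratio was 0.178, and 243 genes (94.2%) lay within 1.5-fold. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.995 and Spearman's rho was 0.993.

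**Figure D4:**
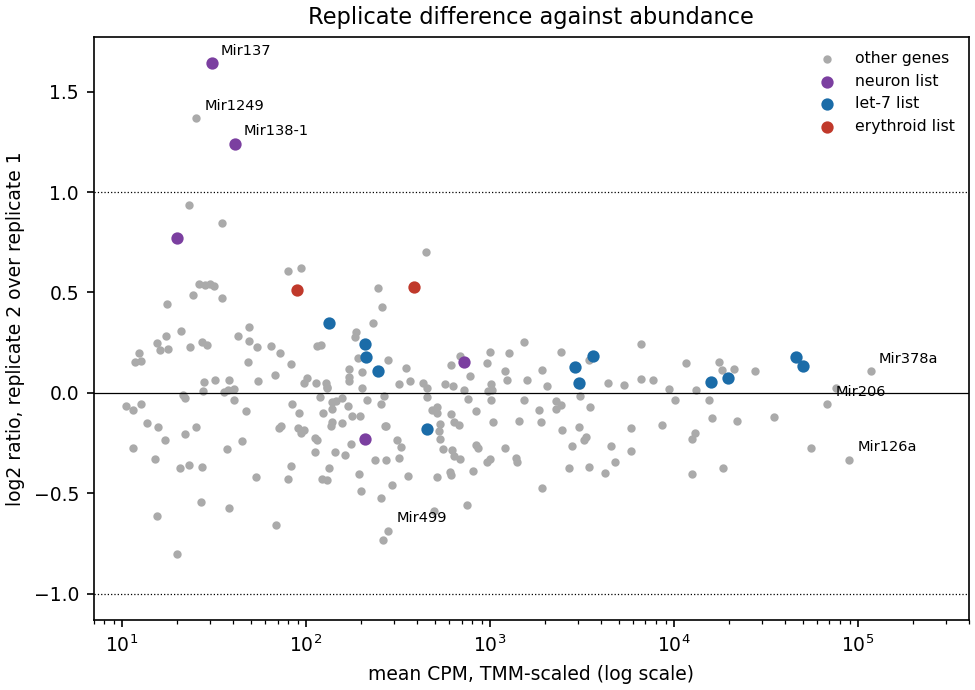
Log2 ratio of replicate 2 over replicate 1 against mean CPM with TMM scaling, on a log axis, for 258 microRNA genes; dotted lines mark a 2-fold difference. Mir137, Mir1249 and Mir138-1 lie above the upper line at 1.64, 1.37 and 1.24, and no gene lies below the lower line.

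Among the fixed lists, the neuron list stood apart. Its median log2 ratio was 0.77 over 5 members, at percentile 99.9 of matched random lists, with Mir137, Mir138-1, Mir138-2 (0.77) and Mir128-1 (0.15) higher and Mir128-2 (−0.23) lower in replicate 2. Adjusted over the list alone, the count was also 4 higher and 1 lower. Mir138-1 and Mir138-2 encode the same mature microRNA, as do Mir128-1 and Mir128-2, so the 5 members are not independent. The summed counts of the list, most of them Mir128-1 and Mir128-2, had a log2 ratio of 0.23 with library sizes from total counts. At 100 CPM or more the list keeps Mir128-1 and Mir128-2 and its median was −0.037, and the glial Mir338 had a log2 ratio of 0.06.

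The let-7 list had a median log2 ratio of 0.13 over 12 members, at percentile 99.7, with 8 members higher and 1 lower in replicate 2. Adjusted over the list alone, the split was 10 and 1, or 8 and 1 with DESeq2 sizes. Mirlet7g (0.18) and Mirlet7i (0.13) were among those higher, and Mirlet7c-2 (−0.18) was the 1 lower. Of the erythroid list, both tested members were higher in replicate 2 (Mir451a 0.53, Mir144 0.51), and both were so adjusted over the list alone.

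Other lists leaned to replicate 1. Of the 46 tested Dlk1-Dio3 members, 27 were lower and 6 higher in replicate 2, and 28 and 6 adjusted over the list alone, with a median of −0.14 at percentile 7.31. With library sizes from total counts 21 were lower and 7 higher. Mir411 (−0.28) was lower, while Mir127 stood at 0.03. The Hox cluster list had a median of −0.29 over 5 members (percentile 3.51, 3 lower), with Mir10b at −0.40, and a median of −0.15 over 6 with any count admitted. The miR-99/100 and miR-125 list had a median of −0.24 over 6 (percentile 3.82, 5 lower), with Mir99a at −0.37. The fibroblast and connective tissue list had 4 of 5 members lower (median −0.14, percentile 13.8), with Mir214 at −0.40, and a median of −0.27 over 6 with any count admitted. The endothelial Mir126a was at −0.33, 98087 CPM in replicate 1 and 80432 CPM in replicate 2. In the Hox, miR-99/100 and miR-125, fibroblast and endothelial lists the counts adjusted over the list alone were the same.

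The myomiRs split, with Mir1a-2 (0.52) and Mir486 (0.14) higher in replicate 2 and Mir499 (−0.69) and Mir206 (−0.05) lower, a median of 0.04 over 8 members. That median turned to −0.15 with either strand counted, −0.05 with any count admitted and −0.06 without the most abundant gene. The muscle growth list had 4 members higher and 5 lower of 15, with a median of 0.01 that was −0.04 to −0.12 under 4 of 6 other settings. In the miR-30 list 3 of 6 members were lower (median −0.09), and in the miR-17-92 list 1 was higher and 3 lower of 8 (median 0.00, with no stable sign). Mir143 of the smooth muscle list (−0.12), Mir146 of the leukocyte list (−0.23) and Mir203 of the epithelial list (−0.43) were lower, each the 1 called member of its list. None of the tested members of the glia, liver and gut lists or of the miR-297, miR-466, miR-467 and miR-669 families passed the exact binomial test, and of 33 tested loci with an identical mature sequence elsewhere 8 were higher and 5 lower. Adjusted over the list alone, none of the counts in these lists changed, and at 100 CPM 1 liver and gut member was higher by that adjustment.

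These splits depend on the scaling. With library sizes from total counts the members higher and lower were 3 and 1 for the myomiRs, 5 and 5 for muscle growth, 10 and 0 for let-7, 4 and 0 for the neuron list and 2 and 2 for miR-17-92. They were then 1 and 2 for miR-30, 1 and 3 for Hox, 0 and 4 for miR-99/100 and miR-125, 1 and 1 for leukocyte, 1 and 0 for liver and gut and 12 and 3 for the loci with an identical mature sequence. Adjusted over the list alone, let-7 was then 10 and 1, the neuron list 4 and 1 and the identical-mature loci 10 and 3. DESeq2 sizes changed Dlk1-Dio3, to 6 and 29, or 6 and 31 over the list alone. They also changed let-7 over the list alone, to 8 and 1. With either strand counted, the number of members tested changes for many lists. The myomiRs were then 0 and 2 of 6, muscle growth 3 and 5 of 15, erythroid 1 and 0 of 1 and Dlk1-Dio3 5 and 21 of 38 (5 and 22 over the list alone). The miR-30 list was 0 and 2 of 5 and the identical-mature loci 6 and 4 of 31.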

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

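Of the tests in this part, those on reads that map to several loci and on expression of the clusters were chosen after the result was seen. Part of the reads was used in no comparison. Reads mapped to several loci were 44.0% of all reads in replicate 1 and 52.1% in replicate 2, which is more than the reads assigned to any gene. Reads that mapped once outside the annotated microRNA genes were 2.90% and 2.68%. On the strand opposite to a microRNA gene, summed over all genes with no annotated partner there, 29 counts were found in replicate 1 and 30 in replicate 2. That is 0.00138% and 0.00176% of the own-strand counts of these genes. The limit given for a gene with no count does not apply to such a sum.

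The reads mapped to several loci bear on the low counts of microRNA genes whose sequence is repeated elsewhere. Repeated genes here are the loci whose mature sequence is identical at another locus, and all others are called single-copy. A single-copy gene can still have 20 bases in common with another locus. In 20 clusters that hold both kinds, the repeated members lay below their neighbours in 17. The median difference was −4.34 in log2(CPM + 1) (95% bootstrap interval −5.37 to −0.56). A two-sided sign-flip permutation test of the mean difference over clusters gave p = 0.001. Some clusters hold copies of the same repeated microRNA, such as Mir24-1 and Mir24-2 or Mirlet7c-1 and Mirlet7c-2. The clusters are therefore not all independent, and the p-value may be too small. Mir24-1 was at 36.0 CPM beside a median of 16128 CPM for Mir23b and Mir27b, which each have 20 bases in common with another locus. Mirlet7c-1 was at 209 CPM beside Mir99a at 18449 CPM, while Mirlet7f-2 and Mir26a-2 were above their neighbours and Mir124a-1 and its neighbour had no count. Some clusters were near the floor, with Mir215 beside Mir194-1 at 0.773 CPM and Mir3093 beside Mir9-1 at 0.226 CPM, each counted among the 17. As a general cause, low expression of the clusters is argued against by the median of 863 CPM for the single-copy neighbours (95% bootstrap interval 71.9 to 5010). The loss of shared reads may therefore account for low values at Mir24, let-7a, let-7c and others, while processing of each hairpin and strain differences from the reference stay open, and no biological explanation was tested.

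The libraries differed by more than counting error. GC content of the hairpin took a share of 0.00118 of the variance of the log2 ratios over 178 genes (upper bootstrap bound 0.0402), against it as the whole cause. A different share of other cells diluting the muscle RNA stays open: the chi-square of 70.1 per degree of freedom within the 46 genes of the Dlk1-Dio3 list does not decide it, since ordinary variation between libraries gives such values over all genes too. Among microRNAs of other cells, Mir451a was at a log2 ratio of 0.53 and Mir126a at −0.33, each a single difference between 2 samples. Blood content, dissection, RNA quality and library preparation were not tested and stay open, and so does a biological difference between the samples.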

How the results depend on the processing

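Shares as percent of all mapped reads and shares without loci that have 20 bases in common with another were chosen after seeing the data; the other settings were planned. With either strand counted, the shares of the myomiR, Dlk1-Dio3, let-7 and 10 most abundant genes were 8.93%, 30.3%, 18.2% and 49.5%, since 25 genes at 10 CPM, holding 23.3% ± 0.426 of counts, lost over 99% of their reads to an opposite-strand partner. With the most abundant gene out of the total they were 7.86%, 27.6%, 16.2% and 53.1%. Of all mapped reads they were 2.42%, 8.52%, 4.96% and 20.5%, a larger denominator. Without loci that have 20 bases in common, which removes Mir378a, Mir411 and Mir23b among the 10 highest, they were 9.34%, 23.0%, 18.6% and 52.2%. Without the identical-mature loci the 10 most abundant genes held 59.3%. All mapped reads as denominator moved all 22 shares by over 1.5 times, muscle growth to 5.32% and endothelial to 3.13% among them. Under the other settings the shares of these further lists moved by over 1.5 times. With either strand counted muscle growth held 4.63%, erythroid 0.0117%, endothelial 5.32e-05% and glia 0%. Muscle growth held 4.02% with the most abundant gene out and 4.03% without loci that have 20 bases in common, and the neuron list 0.00568% without those loci and 0.00424% without the identical-mature loci. By construction the last settings empty or nearly empty the repeated or identical-mature lists. No pancreas or testis gene passes 10 CPM, and testis was 3.64e-05% in replicate 1 alone. In single libraries the first 4 shares were 6.92 to 6.96%, 23.9 to 24.8%, 13.4 to 15.1% and 58.4 to 58.7%.

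The number of genes at 10 CPM ran from 244 (either strand) to 271 (replicate 2 alone), and the coefficient of variation from 11.6% (100 CPM) to 14.2% (any count). The number of genes differing 2-fold was 10 with any count admitted, 0 at 100 CPM and 131 with no fold threshold; it was 3 under both other library sizes, either strand, without the most abundant gene and with edgeR's exact test. Median log2 ratios moved by more than 1 SD of the list's members (for a list with 1 member, of all genes) for the erythroid list (0.57 with total counts, 0.51 with DESeq2 sizes), the neuron list (−0.037 at 100 CPM), the liver and gut list (0.24 at 100 CPM) and the epithelial list (0.35 with either strand and with any count, 0.13 without the most abundant gene). In the last 3 of these lists other genes enter or leave, while the erythroid members have nearly the same ratio, so their SD is small. Within 1 SD, medians close to 0 turned sign under 3 of 6 settings for the myomiR list, 4 for muscle growth, 2 for leukocyte and 3 for miR-17-92. Within 1 SD and with the sign kept, medians moved by over 1.5 times with any count admitted for the endothelial (−0.08), Hox (−0.15), fibroblast (−0.27) and liver and gut (−0.33) lists. They did so with total counts for smooth muscle (−0.03), glia (0.11), miR-30 (−0.04), identical-mature (0.10), the repeated name families (−0.0052) and the 4 lists that turned, and under some other settings for miR-30, muscle growth, leukocyte and miR-17-92. Of 82 named genes, the CPM of 72 moved by more than 1 SD with either strand counted. There the smaller total of assigned counts alone raises the CPM of genes that kept their counts. With TMM or DESeq2 sizes 0 moved, but this outcome was nearly fixed in advance and shows no robustness. Those sizes raise 1 library and lower the other slightly, so a mean over 2 libraries hardly changes. The endothelial and glia medians had no value with either strand counted, and no value of the coefficient of variation, the differing genes or the medians can be had with a replicate left out. No paired analysis was possible because there is 1 group.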

Other observations

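The test over all clusters was planned before its result was seen, and the tests without the Dlk1-Dio3 list were chosen after it. The imprinted loci outside chromosome 12 were chosen after their values were seen. Besides the Dlk1-Dio3 cluster, a set of microRNA genes at other imprinted loci together held 2.27% ± 0.151 of counts, most of it Mir335 in Mest at 17671 CPM. Mir483, in an intron of the fetal growth factor gene Igf2 on chromosome 7, was at 3248 CPM ± 297. Mir298, near Gnas on chromosome 2, was at 1599 CPM ± 88.0 and its neighbour Mir296 at 119 CPM ± 1.56. Mir675, in an exon of the growth-restraining transcript H19, was at 37.0 CPM ± 4.37. MicroRNA genes on chromosome 12 held 24.6% ± 0.681 of counts and those on chromosome X 3.42% ± 0.108.

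Hairpins of 1 cluster were counted at very different levels. Mir23b was 764 ± 39.7 times Mir24-1 and 5.88 ± 1.30 times Mir27b. The count of Mir24-1, whose mature sequence is identical at another locus, leaves out reads that mapped to several loci. Mir127 was 215 ± 46.2 times Mir136, and Mir411 was 2.53 ± 0.168 times Mir379. With either strand counted, Mir191 (5384 CPM ± 232 on its own strand), Mir337, Mir30e, Mirlet7e and Mir486 all had 0 counts in both libraries, beside Mir378a.

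A hypothesis was that neighbouring microRNA genes share the difference between the samples. Over 668 pairs within clusters, the mean product of standardised log2 ratios was 0.219 (one-sided permutation test, p = 0.00061). Without the Dlk1-Dio3 list it was 0.0637 over 83 pairs (one-sided permutation test, p = 0.23), so outside that list the number of pairs leaves the question open, and leaving out also the genes with 20 bases in common gave 0.219 over 39 pairs (one-sided permutation test, p = 0.0705). The first value thus rests mostly on pairs of 1 locus. A shared change of the Dlk1-Dio3 transcript between the samples may account for part of it. Of the 46 tested members, 27 were lower and 6 higher in replicate 2, so they did not all move the same way. A library effect common to the members was not tested.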
